A study of Caenorhabditis elegans with 9 samples.

How the data were processed

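Per the labels' protocols, embryos were obtained by bleaching, hatched in sterile buffer with shaking and collected after 48 h, and total RNA was extracted with Trizol. Per the same labels, biotin-labelled cRNA made from 4 ug of RNA was hybridised to Affymetrix C. elegans arrays, 1 array per culture, for 3 wild type, 3 ogt-1(ok430) and 3 oga-1(ok1207) cultures labelled as biological replicates. The deposited values are log2 probe set summaries that the authors normalised across arrays, as shown by a range of about 4.2 to 14.7 and by array means that differ in the fourth decimal. The submitters' processing notes name MAS5, RMA and Partek without version or role, and which of them made the values is not given in the sources used here. Array values have no count depth, so precision rests on the number of arrays.

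The 77 control probe sets were left out and 22548 probe sets were tested on the deposited log2 scale, with no filter, offset or further normalisation. Gene symbols came from the platform's annotation: 20766 probe sets had 1 symbol, 887 several and 895 none. For tests of lists each gene was read by its brightest 1-symbol probe set, which gave 17118 genes. Of the symbols, 20701 were found in the gene table of assembly WBcel235, and 0 needed a change.

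Differences were tested with limma 3.58.1 in R 4.3.3: lmFit with a mean per strain on all 9 arrays (6 residual degrees of freedom), eBayes (5.65 prior degrees of freedom) and 3 contrasts. A probe set was called at a Benjamini-Hochberg adjusted p under 0.05 within its contrast. Changes of the mutants were compared by the overlap of calls and by the correlation across probe sets. Each was set beside 100 simulated pairs of unchanged groups that shared simulated wild type arrays. The correlation was also set beside splits that gave each mutant its own wild type arrays. The 35 gene lists, with at least 5 measured genes each, cover stress and detoxification, immunity, insulin and dauer signalling, metabolism, large protein complexes, regulators, and markers of neurons, muscle, pharynx, intestine, hypodermis, germline, oocytes and embryos, and sperm. They were tested with limma's camera at a preset correlation of 0.01, adjusted over the lists of a contrast, and again with an estimated correlation. The test fry was also run. It asks whether a list's genes move, on balance, one way and does not compare them with other genes, so its counts are no alternative to camera's. Named genes are ogt-1 and oga-1, the 8 largest rises and the 8 largest falls per contrast among called 1-symbol probe sets with no overlap between the arrays of the 2 strains, and up to 4 members per list by smallest p. For each of these rises and falls, all 3 arrays of 1 strain lie above all 3 of the other. Genes named outside this rule, gcs-1, gst-33 for ogt-1 with wild type and gst-38 for oga-1 with ogt-1, were chosen after their values were seen. Groups, contrasts, lists, the rule for named genes and all alternatives but 2 were set before the data were examined.

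The fit was tested on simulated data with known changes: at 2-fold, 86.6%, 85.1% and 86.6% of changed probe sets were recovered in the contrasts of ogt-1 with wild type, oga-1 with wild type and oga-1 with ogt-1, and 4.94%, 3.77% and 4.24% of calls were false. The simulated noise was independent between probe sets and arrays, without the deviations that real arrays share across probe sets. These shares thus check the fit and do not give the rate of false calls in the real data. Alternatives tried were quantile normalisation, median centring, leaving out the dimmest 25% or 50% of the probe sets, replicate number as a block, a variance trend with robust fitting, fits on 2 strains alone, no variance moderation, stricter thresholds (adjusted p under 0.01, or at least 2-fold), leaving out each array in turn, the other list tests, and the mean of a gene's probe sets. Replicate numbers were checked for pairing by correlating each array's deviation from its strain mean across strains. After seeing the data 2 alternatives were added: the block on 2 strains alone, and wild type replicate 2 and oga-1 replicate 2 both left out. Values for other splits of the arrays were also computed. The highest strain mean of the 5 yeast control probe sets was taken as the level up to which a probe set is not shown to be above background, a choice made after seeing the data. Lower bounds on folds are the ratios of the array values themselves. They hold if background adds to the signal, which was not tested, and they leave out the error of the estimate. Images and probe-level data were not analysed here.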

Results

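RNA was measured in first-stage Caenorhabditis elegans larvae (L1) that hatched without food, in 3 strains with 3 arrays each: wild type, the deletion mutant ogt-1(ok430) and the deletion mutant oga-1(ok1207). OGT-1 is the enzyme that adds the sugar O-GlcNAc to proteins inside the cell, and OGA-1 is the enzyme that takes it off. Per the labels, larvae were collected 48 h after hatching in buffer, and the arrays of a strain are biological replicates. The 9 arrays each carried 22625 probe sets, with array means of 7.36 on the log2 scale and medians from 6.80 to 6.87. Array values rest on hybridisation signal, so the number of arrays limits the precision, and the median standard error of a strain difference was 0.125. The 5 control probe sets for yeast genes, which the larvae lack, read 4.41 to 6.26 (strain means), and the values come without detection calls. Where the mean of the dimmer strain lies at or below 6.26, the level is not shown to be above background, the fold between array values is given as a lower bound (at least), and its rank is one of array values alone. Such a bound concerns background alone and assumes that background adds to the signal. It is a point estimate and not a confidence limit. The 3'/5' log2 ratio of the actin control probe sets, a sign of RNA integrity, was 0.56 ± 0.29 in wild type, 0.52 ± 0.04 in ogt-1 and 0.48 ± 0.13 in oga-1 (SD, n = 3). For actin the strains differed by less than the spread between wild type replicates, but for the other control genes they differed by more. The ratio was 0.59 ± 0.14, 0.39 ± 0.24 and 0.35 ± 0.38 for catalase, 0.105 ± 0.119, -0.033 ± 0.047 and 0.079 ± 0.189 for GAPDH (ogt-1 alone beyond the wild type SD), and 2.94 ± 0.06, 2.86 ± 0.12 and 2.85 ± 0.15 for ubiquitin, in the same order of strains. These ratios thus do not show that RNA integrity was alike. Along the main axis of variation, which held 30.7% of the variance, the 3 wild type arrays lay apart from the 6 mutant arrays, and on the next axis (24.1%) oga-1 replicate 2 lay farthest out, at -36.7. The mean correlation of oga-1 replicate 3 was 0.9894 with its own strain and 0.9906 with the other strains, so the oga-1 arrays do not form a tight group.

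Transcripts of the mutated genes were read from 5 probe sets. For ogt-1, on chromosome III of assembly WBcel235, the dimmer of 2 probe sets read 11.02 ± 0.19 in wild type, 10.41 ± 0.08 on the ogt-1 arrays and 10.62 ± 0.08 on the oga-1 arrays (log2, SD, n = 3). It fell by 0.61 ± 0.11 (SE), or 1.52-fold, on the ogt-1 arrays (adjusted p = 0.0124, 0.00450 to 0.0710 over the alternatives). The call was lost without ogt-1 replicate 2 (adjusted p = 0.0622) or ogt-1 replicate 3 (adjusted p = 0.0710). Its change on the oga-1 arrays was -0.40 (adjusted p = 0.109). The brighter ogt-1 probe set (11.58 in wild type) differed from wild type by -0.22 (adjusted p = 0.581) on the ogt-1 arrays and by -0.42 (adjusted p = 0.240) on the oga-1 arrays. For oga-1, on chromosome X, 3 probe sets were measured. From the dimmest to the brightest, they differed between oga-1 and wild type arrays by 0.03, -0.05 and -0.02 (adjusted p = 0.972, 0.953 and 0.986). Which probes lie inside the deleted parts is not given in the sources used here. The oga-1 transcript level does not tell the oga-1 arrays apart. Neither ogt-1 probe set was called between the mutants, so the ogt-1 level does not tell ogt-1 from oga-1 arrays either. Strains are named by their labels.

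The comparison of ogt-1 with wild type asks which transcripts of starved larvae differ in the strain labelled as deleted for the adding enzyme. The largest rise in array value was in clec-3, a C-type lectin, from 5.57 in wild type to 11.45 on the ogt-1 arrays, at least 58.7-fold (log2 change 5.87 ± 0.12, SE, n = 3, adjusted p = 2.18e-10). It was followed by dod-24, a gene named for acting downstream of the FOXO transcription factor DAF-16, which rose 22.5-fold (4.49 ± 0.16, adjusted p = 3.17e-08), and by F01D5.2, at least 9.35-fold. The C-type lectins clec-74 and clec-73 rose at least 8.12- and 6.77-fold and clec-143 7.38-fold, and the glutathione S-transferases gst-12 and gst-30, which conjugate glutathione to electrophiles, rose 6.87- and 6.39-fold. The largest fall in array value was in pud-4, from 8.17 to 4.93, or at least 9.50-fold (log2 change -3.25 ± 0.19, adjusted p = 2.50e-06). T02B11.4 fell 6.38-fold, tag-293 4.56-fold and the hedgehog-related gene grd-10 at least 3.91-fold. Further falls were those of dach-1, a homologue of the transcription factor Dachshund, 3.82-fold, the lipase-related gene lips-15 3.63-fold and the lysozyme gene lys-4 at least 3.28-fold. The fall of dpf-6, a dipeptidyl peptidase family gene, was 3.80-fold but uneven among the wild type arrays (log2 change -1.93 ± 0.48, adjusted p = 0.0493). Its call was lost without any of ogt-1 replicates 1, 2 and 3 or without oga-1 replicate 1 (adjusted p up to 0.172). The other 15 of these 16 genes passed without each array in turn.

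Glutathione S-transferases rose together on the ogt-1 arrays: of 44 measured genes of the list, which includes gcs-1, the enzyme of the rate-limiting step of glutathione synthesis, 14 rose, 1 fell and 29 did not pass, or 16 higher and 2 lower adjusted over the list alone. Besides gst-12 and gst-30, the oxidative stress reporter gene gst-4 rose 4.82-fold (2.27 ± 0.17), gst-14 rose at least 5.44-fold and gst-6 rose 4.70-fold, and gcs-1 rose by 0.81 (log2). The gene that fell was gst-33 (-0.65, adjusted p = 0.0119), a call lost without ogt-1 replicate 2 or 3 (adjusted p up to 0.0666). Against the other genes the list was shifted up (adjusted p = 1.20e-08, from 6.10e-11 over the alternatives to adjusted p = 0.211 with an estimated correlation). Proteasome subunits were shifted up by a small step, with 29 of 33 genes above 0 and a median of 0.24 (adjusted p = 1.35e-05, from 1.99e-06 over the alternatives to adjusted p = 0.262 with an estimated correlation). The subunits that passed by themselves were pbs-4 (0.46) and rpt-6 (0.54), and 2 passed adjusted over the list alone. Both calls were lost without wild type replicate 2 or 3 or any of ogt-1 replicates 1, 2 and 3 (adjusted p up to 0.0822 and 0.120).

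**Figure D1:**
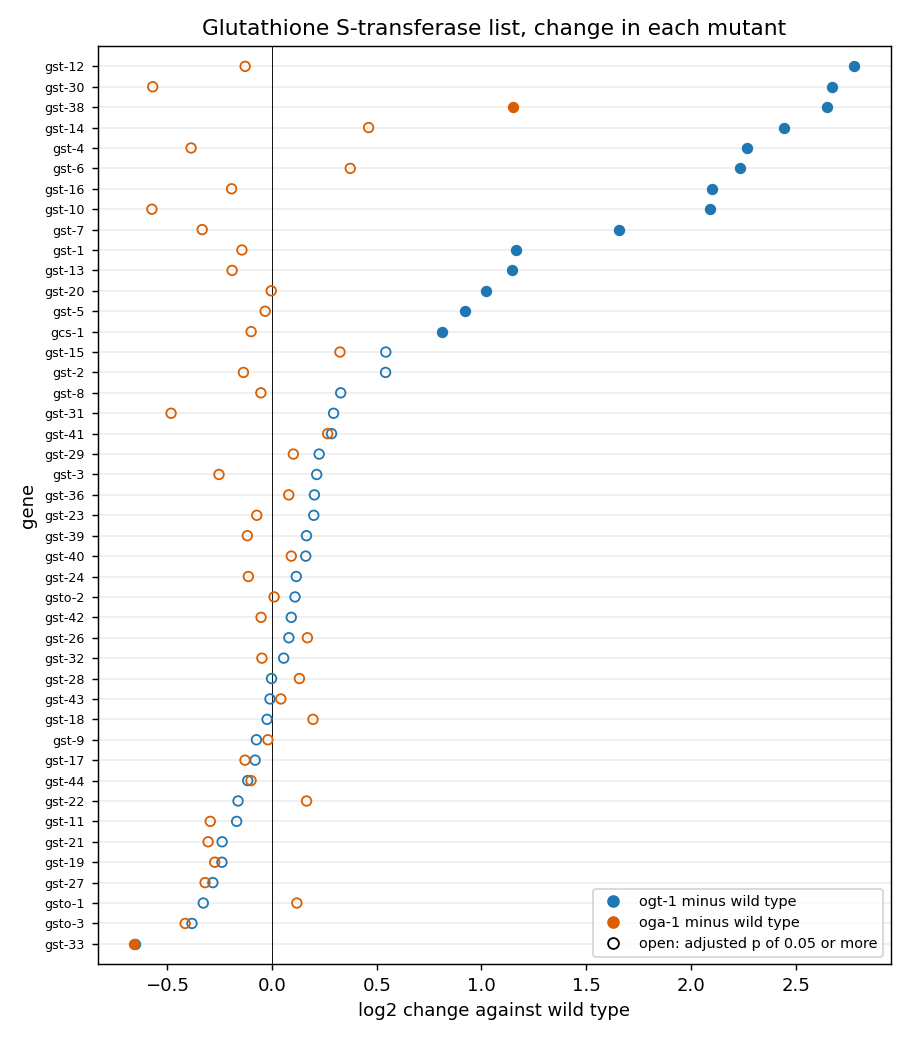
Log2 change against wild type (horizontal axis) of the 44 measured genes of the glutathione S-transferase list (vertical axis, 1 line per gene, sorted by the ogt-1 change), each dot a difference of means of 3 arrays; blue, ogt-1, orange, oga-1, open circles did not pass. On the ogt-1 arrays 14 genes lie at 0.81 or above and passed, while on the oga-1 arrays gst-38 alone passed above 0.

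Some heat shock genes and some genes listed as repressed or activated by DAF-16 also moved. Of 23 heat shock genes, 3 rose on the ogt-1 arrays, the small heat shock genes hsp-12.3 (3.57-fold), hsp-12.6 (2.89-fold) and hsp-16.2 (2.43-fold), and the small heat shock gene sip-1 fell 1.70-fold, with 8 higher and 2 lower adjusted over the list alone. The call of hsp-12.6 was lost without any of ogt-1 replicates 1, 2 and 3 or oga-1 replicate 1 (adjusted p up to 0.143), and that of hsp-16.2 without wild type replicate 1 or 3 or ogt-1 replicate 2 or 3 (adjusted p up to 0.134). The heat shock list was shifted up (adjusted p = 0.00473, from 0.000521 over the alternatives to adjusted p = 0.320 with an estimated correlation). Of 14 genes listed as repressed by DAF-16, dod-24, dod-17 (3.84-fold) and dod-22 (2.82-fold) rose and 11 did not pass, or 5 higher and 0 lower adjusted over the list alone (list adjusted p = 0.00473, from 4.65e-05 over the alternatives to adjusted p = 0.211 with an estimated correlation). In this list 8 genes were above 0, with a median of 0.021 and a mean of 0.605, so a few large rises carry its shift. A dimmer probe set of dod-19, not read for the list, also passed (0.47, adjusted p = 0.0276). Of 16 genes listed as activated by DAF-16, 4 rose and 1 fell, or 7 and 1 adjusted over the list alone, among them the metallothionein mtl-2 (3.06-fold) and the 3 heat shock genes named above, which are in both lists, as is sip-1. This list's shift (adjusted p = 0.0360, from 0.0130 over the alternatives to adjusted p = 0.320 with an estimated correlation) was lost without ogt-1 replicate 3 (adjusted p = 0.0587) and without oga-1 replicate 2.

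Among metabolic genes, the fatty acid desaturases fat-4 (log2 change -0.58), fat-6 (-0.48) and fat-3 (-0.47) fell on the ogt-1 arrays, and 19 of the 22 genes of fatty acid synthesis, desaturation and elongation did not pass, with 4 lower adjusted over the list alone. The list was shifted down (adjusted p = 0.00473, from 0.000386 over the alternatives to adjusted p = 0.211 with an estimated correlation). The gene calls were lost without ogt-1 replicate 2 (all 3 genes), ogt-1 replicates 1 or 3, wild type replicate 3 (fat-6 and fat-3), wild type replicate 2 (fat-6), wild type replicate 1 or oga-1 replicate 1 (fat-3), with adjusted p up to 0.0581, 0.0893 and 0.170 in the order named. Of 73 cytochrome P450 genes 5 fell and none of the others passed, over all genes as well as adjusted over the list alone. The largest fall was in cyp-33C4 (2.11-fold), on a probe set that can bind related transcripts. The shift of this list (adjusted p = 0.0246, from 0.00265 over the alternatives to adjusted p = 0.262 with an estimated correlation) was lost without wild type replicate 1 (adjusted p = 0.0901). Of 64 UDP-glucuronosyltransferases, ugt-13 (at least 4.00-fold) and 1 other rose and 4 fell, or 2 and 6 adjusted over the list alone. The shift down of the list (adjusted p = 0.0329, from 0.00310 over the alternatives to adjusted p = 0.320 with an estimated correlation) was lost without wild type replicate 1, wild type replicate 3 (adjusted p = 0.111) or ogt-1 replicate 3.

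Some tissue marker lists were shifted on the ogt-1 arrays at the preset correlation, with few genes passing. All 15 pharyngeal markers were below 0 on the ogt-1 arrays, with a median of -0.27, and none passed by itself, over all genes or adjusted over the list alone. As a list they were shifted down (adjusted p = 0.00242, from 0.000181 over the alternatives to adjusted p = 0.320 with an estimated correlation). Of 20 body wall muscle markers the myosin heavy chain gene unc-54 rose 1.69-fold (0.76 ± 0.14), the same count as adjusted over the list alone. Of 20 germline markers glh-1, a germ granule helicase, fell by 0.48, with 3 lower adjusted over the list alone. The muscle list (adjusted p = 0.0360, from 0.00118 over the alternatives to adjusted p = 0.718 with an estimated correlation) lost its shift without wild type replicate 2 (adjusted p = 0.300), wild type replicate 3, ogt-1 replicate 2, ogt-1 replicate 3 or oga-1 replicate 2. The germline list (adjusted p = 0.0360, from 0.0191 over the alternatives to adjusted p = 0.262 with an estimated correlation) lost its shift without wild type replicate 3, ogt-1 replicate 3 (adjusted p = 0.146) or oga-1 replicate 2. The gene glh-1 lost its call without any wild type or ogt-1 replicate (1, 2 or 3; adjusted p up to 0.179). Of 147 cuticle collagens, col-142 (2.37-fold) and 1 other rose and 3 fell, the same counts as adjusted over the list alone. The collagens' shift down (adjusted p = 0.0416, from 0.000561 over the alternatives to adjusted p = 0.737 with an estimated correlation) was lost without wild type replicate 1, wild type replicate 2 (adjusted p = 0.493), ogt-1 replicate 1 or oga-1 replicate 2, and with replicate number as a block (adjusted p = 0.0524).

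In all, 882 of 22548 probe sets differed between ogt-1 and wild type, 403 higher and 479 lower on the ogt-1 arrays, and 169 of them by at least 2-fold (97 higher, 72 lower). In 190 of the 882 the dimmer strain mean lay at or below 6.26. With the arrays set to the same median the split was 507 higher and 378 lower, and without wild type replicate 1 it was 357 higher and 295 lower, so which side holds more is not settled. The 3 arrays of 1 strain lay wholly on 1 side of the other 3 for each of the 882 probe sets, and for 5079 of all tested, where chance gives 10%. The count was 332 without ogt-1 replicate 2, 350 without ogt-1 replicate 3, 587 without wild type replicate 2 and 545 without wild type replicate 3. Of the 35 lists, 12 were shifted (6 up, 6 down) and 23 were not (adjusted p from 0.0558 to 0.810). Groupings that mixed these 2 strains gave up to 12 shifted lists. With an estimated correlation camera called 0 lists, and 6 had an unadjusted p under 0.05. The test fry, which asks whether a list moves one way and not whether it moves against the other genes, called 7. The 6 lists just named with calls that rest on particular arrays (DAF-16 activated genes, cytochrome P450s, UDP-glucuronosyltransferases, muscle, germline and collagens) also lost them on quantile-normalised values (adjusted p up to 0.144). Without ogt-1 replicate 1 the number of shifted lists was 19.

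The comparison of oga-1 with wild type asks the same question for the strain labelled as deleted for the removing enzyme. The largest rise in array value was in srw-85, a predicted serpentine receptor, from 5.08 in wild type to 8.84 on the oga-1 arrays, at least 13.5-fold (log2 change 3.75 ± 0.11, SE, n = 3, adjusted p = 1.74e-08). C17H12.8 rose 10.2-fold (3.35 ± 0.14) and sysm-1 6.12-fold (2.61 ± 0.22). Other rises were those of slc-36.4, of a family of amino acid transporters, 4.22-fold, odc-1, the ornithine decarboxylase of polyamine synthesis, 3.48-fold, and the C-type lectin clec-86 3.27-fold. Falls in array value were led by pud-4, at least 7.67-fold (log2 change -2.94 ± 0.19, adjusted p = 2.87e-05), T02B11.4, 4.34-fold, and dach-1, 4.00-fold. C15A11.7, F36G3.2 and F19F10.1 fell 2.88-, 2.53- and 2.48-fold, and ZC395.4 at least 2.59-fold. The genes with calls that rest on particular arrays were R12E2.14 (3.65-fold higher) and R12E2.15 (3.36-fold higher), read by probe sets that can bind related transcripts, and tag-293 (2.51-fold lower). R12E2.14 and R12E2.15 did not pass without any of wild type replicates 1, 2 and 3 or oga-1 replicates 1 and 2, nor R12E2.15 without ogt-1 replicate 3 (adjusted p up to 0.102 and 0.149). Nor did tag-293 pass without wild type replicate 1, wild type replicate 3 or oga-1 replicate 2 (adjusted p up to 0.0755).

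Heat shock genes were shifted up on the oga-1 arrays too: of 23, hsp-12.3 rose 3.02-fold, hsp-16.2 2.40-fold and hsp-4, the chaperone BiP of the endoplasmic reticulum, 1.85-fold, with 6 higher and 1 lower adjusted over the list alone. For heat shock genes as a list the adjusted p was 0.00984, from 0.000491 over the alternatives to adjusted p = 0.522 with an estimated correlation. These 3 genes did not pass without oga-1 replicate 1 or oga-1 replicate 2. Nor did hsp-12.3 and hsp-4 without wild type replicate 2, hsp-16.2 and hsp-4 without wild type replicate 1 or 3, or hsp-16.2 without ogt-1 replicate 2 or 3 (adjusted p up to 0.0677 for hsp-12.3, 0.152 for hsp-16.2 and 0.132 for hsp-4). Of 14 genes listed as repressed by DAF-16, dod-22 rose 3.22-fold and dod-24 1.98-fold, or 4 adjusted over the list alone. A dimmer probe set of dod-19, not read for the list, also passed (0.60, adjusted p = 0.0143). For the repressed genes as a list the adjusted p was 0.00994, from 0.00286 over the alternatives to adjusted p = 0.405 with an estimated correlation. The call of dod-24 was lost without wild type replicate 2 or oga-1 replicate 1 (adjusted p up to 0.0660). Of 16 genes listed as activated by DAF-16, mtl-2 (2.31-fold), hsp-12.3 and hsp-16.2 rose, or 6 adjusted over the list alone. That list's shift (adjusted p = 0.0366, from 0.0105 over the alternatives to adjusted p = 0.522 with an estimated correlation) was lost without oga-1 replicate 1 (adjusted p = 0.0861), without oga-1 replicate 3, and on quantile-normalised values (adjusted p = 0.0620).

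Histone genes were shifted down on the oga-1 arrays: of 26, his-64 (-0.83), his-31 (-0.51) and his-1 (-0.45) fell, each on a probe set that can bind related transcripts, or 4 adjusted over the list alone. The list's shift (adjusted p = 0.00984, from 0.000500 over the alternatives to adjusted p = 0.825 with an estimated correlation) was lost without oga-1 replicate 2 (adjusted p = 0.226). The call of his-1 was lost without each of the 9 arrays in turn (adjusted p up to 0.149). The call of his-31 was kept without ogt-1 replicate 1 and oga-1 replicate 3 alone (up to 0.149), and his-64 lost it without wild type replicate 3 or oga-1 replicate 1 (up to 0.0661). Muscle genes unc-54 (1.75-fold) and myo-3 (1.86-fold), both myosin heavy chains, rose, or 3 of 20 muscle markers adjusted over the list alone. For muscle markers as a list the adjusted p was 0.00984, from 3.50e-05 over the alternatives to adjusted p = 0.825 with an estimated correlation. The muscle list lost its shift without wild type replicate 2 (adjusted p = 0.120), oga-1 replicate 1 or oga-1 replicate 3. The call of unc-54 was lost without oga-1 replicate 1 (adjusted p = 0.0692), and that of myo-3 without each array but wild type replicate 1 (up to 0.182). The 15 pharyngeal markers had a median of -0.25 with 3 above 0 and none passing, over all genes or adjusted over the list alone. Their shift (adjusted p = 0.0198, from 0.00286 over the alternatives to adjusted p = 0.622 with an estimated correlation) was lost without wild type replicate 1 (adjusted p = 0.273), oga-1 replicate 2 or oga-1 replicate 3.

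The desaturase gene fat-4 fell by 0.52 on the oga-1 arrays, and 3 of 22 fatty acid genes fell adjusted over the list alone. For fatty acid genes as a list the adjusted p was 0.0170, from 0.00286 over the alternatives to adjusted p = 0.405 with an estimated correlation. The list lost its shift without wild type replicate 1 or oga-1 replicate 2 (adjusted p = 0.0681), and fat-4 kept its call without ogt-1 replicate 1 and oga-1 replicate 3 alone (adjusted p up to 0.0997 without another). Of 64 UDP-glucuronosyltransferases, ugt-46 (-0.62) and ugt-44 (-0.57) fell, 2 also adjusted over the list alone. For this family as a list the adjusted p was 0.0232, from 0.00157 over the alternatives to adjusted p = 0.522 with an estimated correlation. This list lost its shift without wild type replicate 1 (adjusted p = 0.162), wild type replicate 3 or oga-1 replicate 3. Both ugt-46 and ugt-44 lost their calls without wild type replicate 1 or oga-1 replicate 1, ugt-46 also without wild type replicate 2, and ugt-44 also without wild type replicate 3 or oga-1 replicate 2 (adjusted p up to 0.0873 and 0.116). The 254 nuclear hormone receptor genes were shifted down with a median of -0.06 (adjusted p = 0.0198, from 0.00590 over the alternatives to adjusted p = 0.522 with an estimated correlation), a shift lost without wild type replicate 1 (adjusted p = 0.128). Of the receptor genes that passed, nhr-106 (-0.74) went with the list, while nhr-63 (0.50) and nhr-225 (0.47) went against it, and none passed adjusted over the list alone. The dimmer strain means of nhr-106 (6.17) and nhr-225 (5.99) are not shown to be above background. The calls of nhr-63, nhr-225 and nhr-106 were lost without wild type replicate 1 or 3 or oga-1 replicate 1 or 2, and also without ogt-1 replicate 2. Those of nhr-63 and nhr-225 were also lost without wild type replicate 2 or oga-1 replicate 3, and that of nhr-225 also without ogt-1 replicate 1 or 3 (adjusted p up to 0.109, 0.127 and 0.0880). Glutathione S-transferases as a list did not pass (adjusted p = 0.159). Among them gst-38 rose 2.22-fold and gst-33 fell 1.58-fold, or 1 higher and 2 lower of 44 adjusted over the list alone. The call of gst-38 was lost without wild type replicate 2, and that of gst-33 without wild type replicate 1 or 3, and both without oga-1 replicate 1 or 2 (adjusted p up to 0.0963 and 0.0768).

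In all, 436 probe sets differed between oga-1 and wild type, 164 higher and 272 lower on the oga-1 arrays, and 81 of them by at least 2-fold (45 higher, 36 lower). In 85 of the 436 the dimmer strain mean lay at or below 6.26. All 436 kept the arrays of both strains apart, as did 3716 of all tested, where chance gives 10%. Replicates of the same number varied together in wild type and oga-1 (correlations across probe sets of 0.48, 0.43 and 0.36 for replicates 1, 2 and 3). Deviations from a mean of 3 arrays depend on each other and the arrays can be matched in few ways, so such correlations can arise without pairing. With replicate number as a block the count was 749, or 1316 on these 6 arrays alone, the latter an alternative chosen after seeing the data. It was 124 without oga-1 replicate 1, 262 without oga-1 replicate 2, 262 without ogt-1 replicate 2, and 274, 209 and 259 without wild type replicates 1, 2 and 3. Without wild type replicate 1 the split turned to 154 higher and 120 lower, so the excess of falls depends on that array. Fitted without the ogt-1 arrays it was 187. Of the 35 lists, 9 were shifted (4 up, 5 down) and 26 were not (adjusted p from 0.0596 to 0.974). Groupings that mixed these 2 strains gave up to 12 shifted lists. With an estimated correlation camera called 0 lists, and 2 had an unadjusted p under 0.05, while fry, with its other question, called 1.

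Many changes were shared by both mutants. Of the 436 probe sets that differed in oga-1 and the 882 in ogt-1, 303 went the same way, 98 higher and 205 lower, and 6 went opposite ways. In both mutants pud-4, T02B11.4, dach-1, C15A11.7, ZC395.4, F36G3.2 and F19F10.1 fell, and C17H12.8 (6.08-fold in ogt-1), slc-36.4 (4.38-fold in ogt-1), clec-86 (4.90-fold in ogt-1), odc-1 (2.70-fold in ogt-1), dod-22 and mtl-2 rose. The shared calls were 69.5% of those in oga-1 and 34.4% of those in ogt-1, and independent lists of the same sizes would share 2.93 higher and 5.78 lower. Both mutants were set against the same 3 wild type arrays, which alone makes changes look alike. In 100 simulations of 3 unchanged groups, wild type drawn anew each time, the mean correlation across probe sets was 0.53 (-0.51 to 0.96). The observed correlation was 0.69 (jackknife standard error 0.11). The simulations gave 0 shared calls, but unchanged groups are bound to give few calls, so the 0 says little about the sharing. Probe sets are not independent replicates. With different wild type arrays for each mutant the correlation was 0.36 to 0.44. The number shared was 94 without oga-1 replicate 1, 144 and 165 without ogt-1 replicates 2 and 3, and 193 (95 higher, 98 lower), 158 and 189 without wild type replicates 1, 2 and 3, and it was 470 with replicate number as a block.

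**Figure D2:**
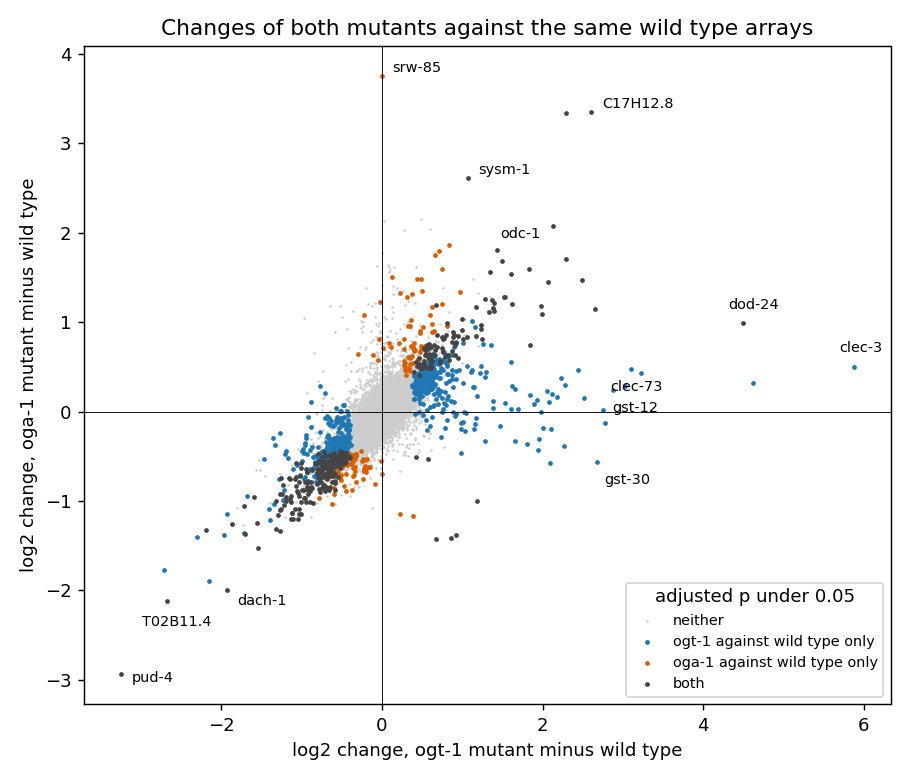
Log2 change against wild type of each probe set in ogt-1 (horizontal axis) and in oga-1 (vertical axis), differences of means of 3 arrays; dark points passed in both comparisons, blue in ogt-1, orange in oga-1, grey in neither. pud-4, T02B11.4 and dach-1 lie at the lower left, clec-3 (5.87 and 0.50) and gst-30 far right near the horizontal axis, and srw-85 (0.00 and 3.75) at the top.

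The direct comparison of oga-1 with ogt-1 asks where the strain labelled as deleted for the removing enzyme differs from that labelled as deleted for the adding enzyme, with no use of the wild type means. The genes that had risen on the ogt-1 arrays dominated: on the oga-1 arrays clec-3 was lower by at least 41.5-fold (log2 difference -5.38 ± 0.12, SE, n = 3, adjusted p = 6.12e-10), dod-24 by 11.3-fold and gst-30 by 9.48-fold. Also lower were gst-12 by 7.51-fold, F01D5.2 by 6.95-fold, clec-73 by at least 6.66-fold, clec-74 by 6.64-fold and gst-10 by 6.33-fold. Higher on the oga-1 arrays were srw-85, at least 13.5-fold (3.76 ± 0.11, adjusted p = 8.67e-09), sysm-1, 2.91-fold (1.54 ± 0.22, adjusted p = 0.00599), and the beta-tubulin gene tbb-6, 2.61-fold (1.39 ± 0.17, adjusted p = 0.00174). F14H12.3 (at least 2.47-fold), pqn-71 (3.54-fold), C50F7.5 (2.93-fold), the cuticle collagen gene col-113 (at least 2.36-fold) and the cathepsin-like protease gene cpr-1 (2.21-fold) were higher with calls that rest on particular arrays. None of these 5 genes passed without oga-1 replicate 1. F14H12.3, pqn-71, C50F7.5 and col-113 did not pass without ogt-1 replicate 1, nor pqn-71, C50F7.5, col-113 and cpr-1 without ogt-1 replicate 2 or 3. Nor did pqn-71, C50F7.5 and cpr-1 pass without oga-1 replicate 2, nor pqn-71 and C50F7.5 without wild type replicate 2, nor cpr-1 without wild type replicate 1 or oga-1 replicate 3 (adjusted p up to 0.0639, 0.227, 0.183, 0.141 and 0.238 in the order first named). C50F7.5 was read by 3 probe sets, and the change given is that of the brightest alone. The other probe sets, dimmer at wild type levels of 4.92 and 4.66 against 7.48, differed from wild type by -0.08 and 0.05 on the ogt-1 arrays and by -0.02 and 0.05 on the oga-1 arrays, none passing.

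Of the 44 genes of the glutathione S-transferase list, 13, gcs-1 among them, were lower and 0 higher on the oga-1 arrays than on the ogt-1 arrays. Adjusted over the list alone the counts were 17 and 0. The lower genes included gst-4 (6.30-fold), gst-16 (at least 4.90-fold) and gst-38 (2.82-fold). The list was shifted down (adjusted p = 3.08e-25, from 1.78e-28 over the alternatives to adjusted p = 0.0527 with an estimated correlation). Among 33 proteasome subunits 1 was above 0, the median was -0.17 and none passed by itself, over all genes or adjusted over the list alone. For proteasome subunits as a list the adjusted p was 1.70e-09, from 1.58e-10 over the alternatives to adjusted p = 0.119 with an estimated correlation. Germline markers were shifted up with 17 of 20 above 0, none passing over all genes and 2 higher adjusted over the list alone. For germline markers as a list the adjusted p was 0.000587, from 1.09e-05 over the alternatives to adjusted p = 0.0886 with an estimated correlation. The largest of their differences were those of glh-1 (0.55, adjusted p = 0.0855, and 0.0238 without oga-1 replicate 3) and pgl-1 (0.50, adjusted p = 0.0933), which encode germ granule proteins. Sperm markers had 36 of 39 genes above 0 and none passing, over all genes or adjusted over the list alone. Members such as msp-3, msp-53 and msp-59 were read by probe sets that can bind related transcripts. The list's estimated correlation, 0.42, was the highest of all lists, so the 36 are not separate readings. The levels of these genes were not set beside the yeast controls, so a shift of this list is not shown to be one of sperm RNA. The shift up of the sperm list (adjusted p = 0.00157, from 4.30e-07 over the alternatives to adjusted p = 0.757 with an estimated correlation) was lost without oga-1 replicate 1 (adjusted p = 0.228).

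Of 147 cuticle collagens col-113 was higher and col-76 lower (-1.02), the same counts as adjusted over the list alone. The list was shifted up (adjusted p = 0.00312, from 4.30e-07 over the alternatives to adjusted p = 0.835 with an estimated correlation). The shift was lost without ogt-1 replicate 1 (adjusted p = 0.241), oga-1 replicate 1 or oga-1 replicate 2. The call of col-76 was lost without ogt-1 replicate 2 or 3 or oga-1 replicate 1 (adjusted p up to 0.126). Of 65 antimicrobial genes the lysozyme gene lys-3 was higher (0.65), with 3 higher and 1 lower adjusted over the list alone. The call of lys-3 was kept without ogt-1 replicate 2 alone (adjusted p up to 0.266 without another array). That list's shift up (adjusted p = 0.0268, from 0.00249 over the alternatives to adjusted p = 0.119 with an estimated correlation) was lost without ogt-1 replicate 1, ogt-1 replicate 3 (adjusted p = 0.107) or oga-1 replicate 1. On quantile-normalised values the sperm, collagen and antimicrobial lists each had an adjusted p of 0.0545.

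In all, 116 probe sets differed between the mutants, 33 higher and 83 lower on the oga-1 arrays, and 74 of them by at least 2-fold (13 higher, 61 lower). In 34 of the 116 the dimmer strain mean lay at or below 6.26. All 116 kept the arrays of both strains apart, as did 2225 of the 22548 tested, no more than the 10% that chance gives. The count was 197 without oga-1 replicate 3, where the split turned to 106 higher and 91 lower. It was 76 without ogt-1 replicate 2, 77 without ogt-1 replicate 3 and 176 with replicate number as a block. Of the 35 lists, 6 were shifted (4 up, 2 down) and 29 were not (adjusted p from 0.101 to 0.939), and the number was 12 without oga-1 replicate 2 and 11 without oga-1 replicate 3. Groupings that mixed these 2 strains gave up to 13 shifted lists. With an estimated correlation camera called 0 lists, and 4 had an unadjusted p under 0.05, while fry, with its other question, called 5.

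**Figure D3:**
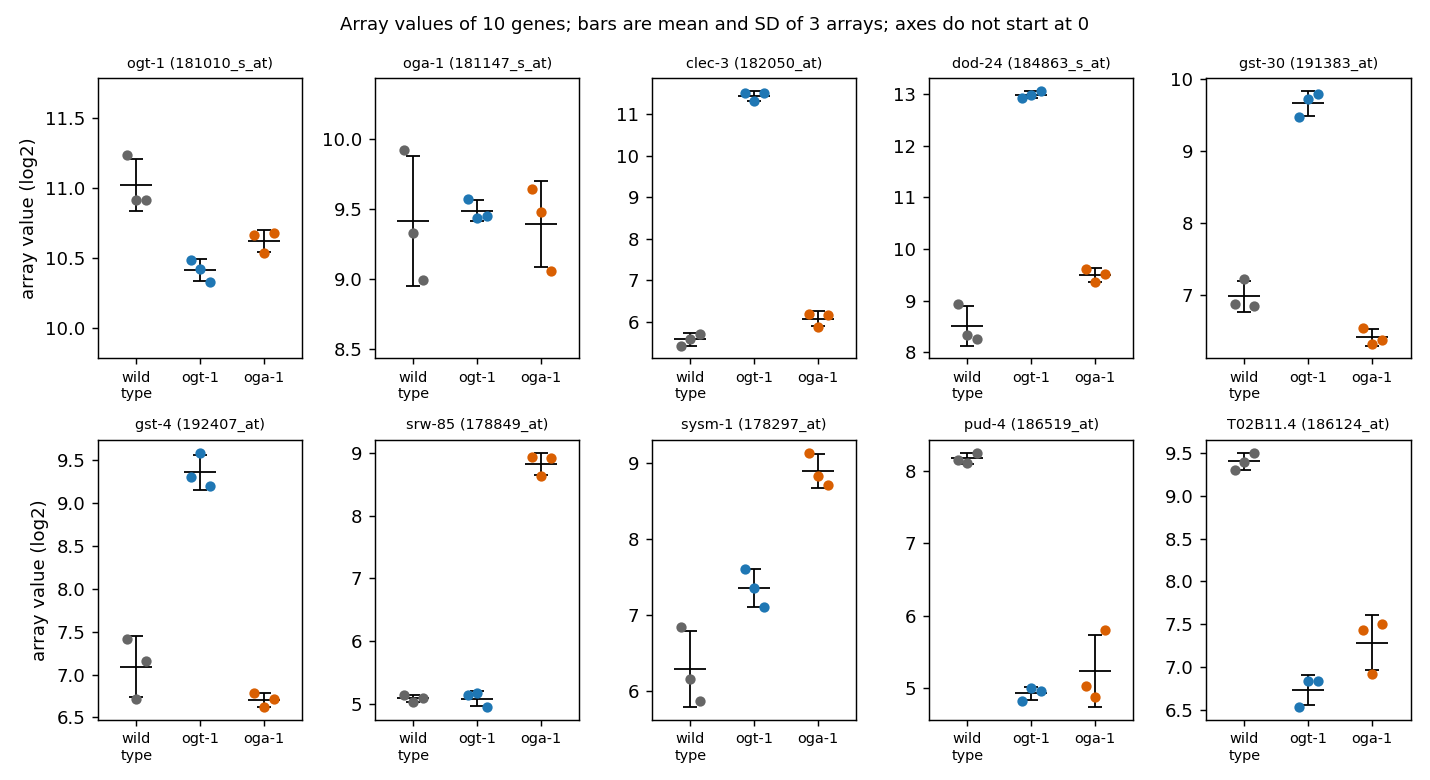
Log2 array values (vertical axes, which do not start at 0) of 10 genes on the 3 arrays of each strain (dots), with the mean and SD (bars). clec-3, dod-24, gst-30 and gst-4 are high on the 3 ogt-1 arrays, srw-85 and sysm-1 on the 3 oga-1 arrays, and pud-4 and T02B11.4 are low on the arrays of both mutants.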

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

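The tests of the glutathione S-transferase rise and of the changes shared by the mutants were chosen after these results were seen, except the counts over other splits of the arrays; those of the probe sets with opposite changes were written before, but the interval of their lowest correlation, the grouping of the pairs and the runs for their opposite calls were added after.

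Of all probe sets, 6 changed in opposite directions in the 2 mutants, and the difference between the mutants itself passed for each, in 3 of 3 arrays against 3 of 3. Since these probe sets were chosen by opposite calls in both mutants, that passing follows largely from the choice and is no separate support. The oga-1 minus ogt-1 difference was -2.30, -2.28, -2.105 and -1.11 for 4 probe sets with no gene named in the sources used here, with wild type levels of 7.33, 8.09, 7.74 and 5.28 (adjusted p = 2.84e-06, 1.52e-06, 9.77e-07 and 9.75e-05). It was -2.185 for a probe set (adjusted p = 2.43e-05) that reads nspa-1, nspa-2, nspa-3, nspa-4, nspa-5, nspa-8 and nspa-12, of a nematode-specific peptide family, and -0.93 for ZK742.4 (adjusted p = 0.000774). Against wild type the nspa probe set rose by 1.19 in ogt-1 and fell by 1.00 in oga-1. The dimmer means of those at -2.30 and -1.11, 5.96 and 4.74 on the oga-1 arrays, lie at or below the highest yeast control (6.26) and are not shown to be above background. For the difference between the mutants, 6 of 6 passed in all 9 runs without 1 array (highest adjusted p = 0.00810), which argues against a lone array. The choice of probe sets made such passing likely, so these runs are weak evidence. The opposite calls against wild type are less firm: the signs stayed opposite for all 6 in each run, but both calls held for 4 without wild type replicate 1, 2 or 3, ogt-1 replicate 2 or oga-1 replicate 1, for 5 without ogt-1 replicate 1 or 3 or oga-1 replicate 3, and for 6 without oga-1 replicate 2. That 1 transcript family was read by several probe sets stays open: the lowest of 15 correlations between pairs, within strains over the 9 arrays, was -0.42, with a 95% interval of -0.89 to 0.48, and the median was 0.36. The 5 pairs with the nspa probe set ran from -0.42 to -0.02, while the 10 pairs among the others ran from 0.12 to 0.68. That goes with 1 family among the others and the nspa probe set apart from it, but too few arrays stand behind each pair to settle it. A lowest correlation under 0 was set beforehand as a value against it, but the lowest of 15 with 6 residual degrees of freedom can fall below 0 by noise. The mutations themselves, or other differences carried by the strains, stay open and untested.

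Of the 44 genes of the glutathione S-transferase list, 14, gcs-1 among them, rose on the ogt-1 arrays. Probe sets shared between family members are argued against as the whole cause, since 11 of the 14 genes were read by probe sets designed for 1 gene. More RNA from the intestine would raise its markers by about as much, but the median change of 16 intestinal markers was -0.0046 (SD 0.51). The smallest change of a called member was 0.81 (gcs-1), and the median of those called was 2.095. That the ogt-1 arrays were prepared apart cannot be told apart from the mutation. Arrays of the same number correlated between wild type and oga-1 (lowest correlation 0.36) and less with ogt-1 (highest 0.11), and the labels name no preparation. With so few arrays per strain, such correlations can also arise without pairing. A response to the ogt-1 mutation may thus account for the rise, as may a preparation difference.

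The mutants shared 303 changes. Over 100 splits of the 9 arrays into groups of 3, 1 split, the real one, gave as many shared calls (highest other 57). The other splits mix strains, which widens the spread within groups and lowers the number of calls. The count thus cannot tell whether the sharing comes from the common wild type arrays. For the correlation of 0.69, 13 of 100 splits gave as much (highest other 0.82), so chance is not excluded. These splits and the simulated groups take the arrays as independent, although wild type and oga-1 arrays of the same number deviated together in all 3 pairs (0.48, 0.43 and 0.36). Chance values of the shared wild type arrays stay open for the count and the correlation. The lowest covariance with separate wild type arrays, 0.0298, lies below the highest simulated one, 0.0631. Setting the lowest value against the highest is a strict bar. The simulated mean was 0.00067, and 36 simulated values reached 0.0298, from 100 simulations with 6 splits each. Wild type cultures that differed from both mutants for another reason, on the axis with 30.7% of the variance, cannot be told apart from a shared effect of both mutations, because 1 set of wild type cultures served both. Either could be a source.

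For the counts of called probe sets, 1 of 10 splits of the 6 arrays, the real one, gave as many in each comparison (882, 436 and 116 against a highest other of 0 each), and 10 splits are too few for a share under 0.05. The numbers of shifted lists were reached by 3 of 10 splits for ogt-1 with wild type (12, highest other 12). They were reached by 6 of 10 for oga-1 with wild type (9, highest other 12) and 7 of 10 for oga-1 with ogt-1 (6, highest other 13). In each comparison some mixed groupings thus gave as many shifted lists as the real one, or more. The numbers of shifted lists therefore do not set the real groupings apart, and 10 splits are also too few for a share under 0.05.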

How the results depend on the processing

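The fits with a replicate block on 2 strains alone and without the pair of arrays numbered 2 were chosen after the results were seen. Of the named gene results, 2326 kept direction and side of the threshold over the alternatives, 533 kept direction but no longer passed, 1 passed only in an alternative and 0 reversed; of the list results by camera these were 444, 95 and 0. The test fry, which compares no list with other genes and so counts something else, called 7 and 1 lists for the mutants against wild type. For ogt-1 with wild type, oga-1 with wild type, oga-1 with ogt-1 and the changes shared by both mutants, the main counts were 882, 436, 116 and 303. Stricter thresholds lowered them by construction, at least 2-fold to 169, 81, 74 and 51, and an adjusted p under 0.01 to 306, 81 and (shared) 61. No variance moderation gave 283, 69, 51 and 57. A replicate block gave 749 for oga-1 with wild type, 176 between mutants and 470 shared, and on 2 strains alone 1316 for oga-1 with wild type and 496 shared. Fits on 2 strains alone gave 187 and 138 for these, but 946 for ogt-1 with wild type and 117 between mutants, and leaving out wild type and oga-1 replicates 2 gave 138 and 1.2e+02. Without each array in turn the counts ran 332 to 1186, 124 to 624, 76 to 197 and 94 to 326, the correlation 0.60 to 0.74, and shifted lists 8 to 19, 6 to 10 and 4 to 12 (main 12, 9 and 6). An estimated correlation called 0, 0 and 0 lists, and quantile normalisation 7 for ogt-1 with wild type and 3 between mutants. The dimmer ogt-1 probe set, at -0.61, lost its call with no variance moderation (adjusted p = 0.0579, over the alternatives 0.00450 to 0.0710) and ran from -0.66 to -0.50 without each array. The brighter ran from -0.30 to -0.08. The oga-1 probe sets, uncalled, changed sign without some arrays, from -0.10 to 0.21 (dimmest), -0.19 to 0.10 and -0.23 to 0.23 (brightest). Where no construction is named the cause was not tested. A pseudocount was not run, since the values are on the log2 scale. Signal over background limits the dimmer genes: yeast control probe sets read 4.41 to 6.26 (strain means), and the dimmer strain mean lay at or below 6.26 in 190, 85 and 34 of the called probe sets of the 3 comparisons. Their folds are lower bounds if background adds to the signal, the error of the estimate aside.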

Other observations

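The tests of genes near the mutated loci were chosen after the results were seen. Of 15 genes of the glyoxylate cycle, trehalose and glycogen, 2 rose, 1 fell and 12 did not pass on the ogt-1 arrays, and 2 rose and 13 did not pass on the oga-1 arrays, without a shift of the list. The trehalase gene tre-2 rose 3.05-fold on the ogt-1 arrays (log2 change 1.61 ± 0.30, adjusted p = 0.0119) and 2.91-fold on the oga-1 arrays (1.54 ± 0.30, adjusted p = 0.0253). Of the acid alpha-glucosidase genes, which act on glycogen, aagr-2 rose in both (0.91 and 0.74), while aagr-1 fell by 1.47 on the ogt-1 arrays and was higher by 0.93 on the oga-1 than on the ogt-1 arrays, and aagr-3 and aagr-4 did not pass in any comparison. The call of tre-2 on the oga-1 arrays was lost without wild type replicate 1 or 2 or oga-1 replicate 1 (adjusted p up to 0.104), and the difference of aagr-1 without wild type replicate 2, ogt-1 replicate 2 or 3 or oga-1 replicate 1 or 3 (up to 0.182). Of 68 genes of lipid mobilisation and beta-oxidation, 4 fell on the ogt-1 arrays and 2 on the oga-1 arrays, the same counts as adjusted over the list alone; the enoyl-CoA hydratase gene ech-7 fell by 1.07 on the ogt-1 arrays. The gluconeogenesis gene pck-1 read 0.68 higher on the ogt-1 arrays and 0.72 higher on the oga-1 arrays. Both calls were lost without wild type replicate 2 or 3 or ogt-1 replicate 2 or 3, and the oga-1 call also without oga-1 replicate 1 (adjusted p up to 0.114 and 0.129).

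Immune genes went both ways. Of 220 C-type lectins, 13 rose and 12 fell on the ogt-1 arrays, or 15 and 20 adjusted over the list alone, with a median of -0.03 and a mean of 0.04 and no shift of the list (adjusted p = 0.810). On the oga-1 arrays 7 rose and 5 fell, or 10 and 10 adjusted over the list alone. Between the mutants 7 were lower and 0 higher on the oga-1 arrays, or 9 and 1 adjusted over the list alone. Of 65 antimicrobial genes, 3 rose and 4 fell on the ogt-1 arrays, or 6 and 7 adjusted over the list alone, and 2 rose and 2 fell on the oga-1 arrays, or 4 and 2. Among them irg-3 (2.28-fold) and lys-2 (1.92-fold) rose on the ogt-1 arrays, and lys-4 (at least 3.28-fold) and the saposin-like gene spp-6 (2.16-fold) fell. On the oga-1 arrays irg-1 rose at least 2.30-fold and lys-2 1.80-fold, and spp-6 fell 2.31-fold and lys-4 2.08-fold. The calls of irg-1 and lys-2 on the oga-1 arrays were lost without oga-1 replicate 1, and that of lys-2 also without wild type replicate 2 (adjusted p up to 0.0666 and 0.101).

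In none of the comparisons did 19 of the 35 lists pass. For 12 of them no gene was called on the probe set read for the list (list adjusted p from 0.0558 to 0.974). These cover O-GlcNAc cycling and hexosamine synthesis, insulin-like signalling components, insulin-like peptides, p38 and JNK kinases, ribosomal proteins, autophagy and dauer signalling. They also cover cell cycle and DNA replication, and the markers of neurons, hypodermis, oocytes and embryos, and yolk. The dimmer ogt-1 probe set, not read for the O-GlcNAc list, was called on the ogt-1 arrays (-0.61, adjusted p = 0.0124). Among the 7 others, besides those named, oxidative phosphorylation held cox-15 (0.48), Polycomb and Hox genes held mig-32 (0.51) and intestinal markers held mtl-2, each higher on the ogt-1 arrays. The intestinal markers also held gly-13, lower on the ogt-1 arrays (-0.48, adjusted p = 0.0358), a call lost without wild type replicate 2 or 3, ogt-1 replicate 1, 2 or 3 or oga-1 replicate 1 (adjusted p up to 0.136). The calls of cox-15 and mig-32 were lost without ogt-1 replicate 1, 2 or 3, wild type replicate 2 or 3 or oga-1 replicate 1, and that of cox-15 without wild type replicate 1 (adjusted p up to 0.165 each).

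Sequence differences carried along with each deletion through crossing might place called genes near the mutated gene. Among the 200 measured genes nearest ogt-1 on chromosome III of assembly WBcel235, 9 were called (4.50%). Of the other 16917, 730 were called (4.32%, 2-sided Fisher's exact p = 0.860, adjusted p = 1), so no clear excess was seen. Near oga-1 on chromosome X 4 of 200 were called (2.00%), against 358 of 16917 (2.12%, 2-sided Fisher's exact p = 1), which shows no excess there. For both genes the idea stays open for a few neighbours, which such shares could not show.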
